A study of Rattus norvegicus with 16 samples.

How the data were processed

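Gene expression in the hypothalamus was measured in 16 male Wistar rats aged 7 to 8 weeks, on 1 single-colour Affymetrix array per rat, per the labels. The groups were control rats, rats restrained for 2 h, rats that inhaled (R)-(-)-linalool for 2 h, and rats that had both for 2 h, with 4 rats in each. Linalool is a monoterpene alcohol with a floral odour, found in lavender oil among others, and (R)-(-) names 1 of its mirror-image forms. Per the labels' protocols, total RNA was extracted with TRIzol, cleaned on a column for lipid-rich tissue and made into biotin-labelled cRNA by the standard procedure of the array's maker.

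The values used were the authors' deposited table of signal intensity, with 31099 probe sets. MAS5, Affymetrix's algorithm that combines the perfect-match and mismatch probes of a probe set into 1 linear signal, is named per the submitters' processing notes, with no version. Its scaling target is not given in the sources used here. The deposited intensity values were all positive, reached 19430 and were not at a common level between arrays. Their mean after trimming 2% at each end ran from 172.6 (control rat 2) to 327.8 (stress rat 2), and the median of a column from 67.03 to 127.4. The fixed design had assumed a table already comparable between arrays. Because the values were not, the log2 values were quantile-normalized between arrays, transformed back, raised by a pseudocount of 16 and taken as log2 again. The values as deposited were kept as an alternative. Probe sets that are spike-in or housekeeping controls (57) were left out. Probe sets were kept where the mean log2 value over all arrays was at or above the 40th percentile, which left 18625. A fold change is therefore on the log2(value + 16) scale and understates the change of dim genes. Quantile normalization gives each array the same distribution of values, so a change shared by most transcripts cannot be seen.

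Gene names came from the platform's annotation table. Of 31042 probe sets, 20826 had 1 gene symbol, 436 had several and 9780 had none in the table used here. No name was taken from a probe set with several symbols. The symbols were compared with a current gene table through their gene IDs, which changed 0 symbols, with 68 IDs not in that table. A gene with several kept probe sets was represented by the brightest one over all arrays. The kept probe sets named 10309 distinct genes.

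Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided) on 1 group-means model over all arrays, with 12 residual and 3.97 prior degrees of freedom. P-values were adjusted by the Benjamini-Hochberg method over the kept probe sets of each comparison, and a call is an adjusted p under 0.05. The 8 comparisons were stress minus control, linalool minus control, stress with linalool minus stress, stress with linalool minus linalool, stress with linalool minus control, the stress effect averaged over both odour conditions, the linalool effect averaged over both stress conditions, and the interaction. The labels assign a separate rat to each array, so that the p-values measure the spread between rats. For arrays, no read depth exists, and the number of arrays limits the precision.

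Lists of pathway genes (15) and of markers of cell types and neighbouring tissues (13) were written before the data were examined. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the 28 lists of a comparison. List members were also counted after adjustment over the list alone. The rule for the genes named in the text was also fixed then. Per comparison, it took the 10 largest rises and 10 largest falls among the called genes, up to 4 called members of each list, 3 members of each list past camera's threshold, the 5 smallest p-values where fewer than 5 genes were called, and always Crh, Avp, Fos, Nr4a1, Sgk1, Fkbp5 and Per1. Names that only number a predicted gene were left out. Whether linalool altered the change with stress was tested as the median interaction over the probe sets called for the average stress effect, signed by the direction of that effect, with an exact permutation test that reassigned the linalool label within the restrained and the unrestrained rats. The same kind of exact test served for the correlation between effects that share no arrays.

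The fit was checked on simulated data with 200 of 18625 probe sets changed, in 5 runs. Their noise was drawn from a normal distribution, independently for each probe set and with the same spread in all groups. Measured genes can be correlated, at an estimated 0.301 within the heat shock list for stress minus control, and can spread unequally between groups. The shares below hold for the simulated setting and need not hold for the measured data. For stress minus control, 92.8% of the probe sets raised by 1 on the log2 scale were called, and 51.2% of those raised by 0.5, with 6.17% of the calls false. For stress with linalool minus stress these shares were 91.6%, 49.6% and 4.92%, for stress with linalool minus linalool 92.4%, 52.8% and 5.68%, and for the average stress effect 98.4%, 79.6% and 4.57%.

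A technical split was found in the spike-in controls added before hybridization. The BioC 3' signal was 884.4 to 1014 on 3 arrays (linalool rats 2 and 4 and stress with linalool rat 2) and 201.3 to 271.4 on the other 13, below called the BioC-high and BioC-low arrays. The BioC 5' (701.5 to 797.1 against 195.2 to 256.5) and BioB 3' (267.2 to 287.2 against 162.9 to 249.7) signals split the same arrays. The BioDn 3' (2748 to 3329 against 2428 to 2916) and CreX 3' (8321 to 9332 against 8214 to 9208) signals overlapped. What the split reflects is thus not known. Every comparison was repeated with the BioC split as a block and within the BioC-low arrays, and stress with linalool minus linalool also within the BioC-high arrays. Control rat 1 had the highest 3'/5' signal ratios, a sign of RNA quality, at 4.927 for beta-actin and 1.394 for GAPDH, and control rat 2 the dimmest array. The beta-actin ratio as a covariate and a fit without both control arrays were therefore added. No label names a hybridization batch. Quantile normalization and these alternatives were chosen after seeing the data, whereas the values as deposited are the setting that had been fixed before. Those fixed before were a pseudocount of 1 or 64, no filter, a filter at the 60th percentile, centring on the median in place of quantile normalization, a trended and robust eBayes step, array weights, a fit of only the groups compared, the replicate number as a block, and leaving out each array in turn.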

Results

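Signal intensities of the hypothalamus were compared in 16 rats, 4 in each of 4 groups. The groups were untreated controls, rats restrained for 2 h, rats that inhaled (R)-(-)-linalool for 2 h, and rats that had both together. The 2 × 2 layout asks which transcripts restraint changed, which linalool changed, and whether the change with restraint differed when the odour was present. Median signals per array lay between 67.03 and 127.4 before normalization. The BioC hybridization spike-in was 884.4 to 1014 on 3 arrays (linalool rats 2 and 4 and stress with linalool rat 2, the BioC-high arrays) and 201.3 to 271.4 on the other 13, so results are also given with this split as a block and within the BioC-low arrays. It is treated as a possible hybridization batch and called the BioC batch below, although no label names one. Group means below are on the log2(signal + 16) scale with the SD over 4 rats, and changes are log2 differences with limma's standard error (SE) and Benjamini-Hochberg adjusted p.

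Restraint without odour raised genes of the glucocorticoid response. Sgk1, a kinase gene induced by glucocorticoids, rose from 9.54 ± 0.19 in controls to 11.81 ± 0.17 in restrained rats (n = 4), a 4.83-fold change (log2 2.27, SE 0.12, adjusted p = 4.04e-08). Pdk4, which restrains pyruvate use, rose by 2.01 (SE 0.17, adjusted p = 2.17e-05), and Ddit4, an inhibitor of mTOR signalling, by 1.33 (SE 0.12, adjusted p = 4.26e-05). Errfi1 (1.26), Fkbp5, a chaperone that tempers the glucocorticoid receptor (0.93), the clock genes Per1 (1.11) and Per2 (0.43), and Nfkbia, the inhibitor of NF-kappaB (1.30), rose as well. Of 30 measured genes on the glucocorticoid-responsive list, 15 rose and 0 fell, with 24 higher when adjusted over the list alone. The list's median change was 0.67, with a camera adjusted p of 1.26e-37, and an adjusted p = 0.00111 with an estimated correlation.

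Heat shock genes rose in the same comparison. Hspa1a, an inducible heat shock protein 70 gene whose sequence is nearly identical to that of Hspa1b, so that their signals cannot be kept apart with certainty, went from 7.33 ± 0.05 to 10.76 ± 1.54 (n = 4; log2 3.44, SE 0.54, adjusted p = 0.00631). Dnajb1, its cochaperone, rose by 1.28 (adjusted p = 0.00671), Cryab, a small heat shock protein, by 0.75 (adjusted p = 0.0146), and Hspa5, the chaperone of the endoplasmic reticulum, by 0.49 (adjusted p = 0.0228). Of the 24 measured members of the heat shock list, 5 rose and 0 fell, and 16 were higher when adjusted over the list alone. Its median change was 0.31, with a camera adjusted p of 7.97e-18 and an adjusted p = 0.0594 with an estimated correlation. Among 26 immediate early genes, those switched on within minutes of neuronal activity, Gadd45g rose (0.70, adjusted p = 0.045). Fos (0.62, SE 0.29, adjusted p = 0.39) and Nr4a1 (0.33, SE 0.29, adjusted p = 0.696) did not pass. With 5 members higher when adjusted over the list alone, the immediate early list had a median of 0.32, a camera adjusted p of 3.09e-05, and an adjusted p = 0.329 with an estimated correlation.

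The genes that fell under restraint alone included several known from microglia. Gpr34, a lysophospholipid receptor, fell by 1.27 (SE 0.23, adjusted p = 0.0145), P2ry12, the ADP receptor that steers microglial processes, fell by 0.95 (SE 0.18, adjusted p = 0.0172), and Cd33, an inhibitory sialic acid receptor, fell by 0.86 (SE 0.15, adjusted p = 0.0121). Bin2 and Plek, both genes of blood-derived and microglial cells, fell by 1.02 and 0.96. Nrarp, a target and inhibitor of Notch signalling, fell by 0.86 (adjusted p = 0.00667), and Swi5, Frg1, Rnf6 and Vof16 fell by 0.80 to 0.87. Of 11 measured microglia markers on the fixed list, 1 fell and 0 rose, with 1 higher and 2 lower when adjusted over the list alone, and the list's median of -0.15 did not pass (camera adjusted p = 0.159). The releasing hormone of the stress axis, Crh (-0.08, SE 0.17, adjusted p = 0.906), and vasopressin, Avp (0.03, SE 0.23, adjusted p = 0.97), did not pass, nor did any of 9 measured genes of the stress hormone list. Among other named genes, Gpd1 rose by 1.44, Plekhf1 by 1.07, Ddc, the enzyme that forms dopamine and serotonin, by 0.70, and Ddit3, of the endoplasmic reticulum stress response, by 0.58. Camera also called the glutamate (median -0.167), GABA (-0.18), oxidative phosphorylation (-0.048) and oxidative stress and hypoxia (0.073) lists. Their camera adjusted p of 0.00416, 0.0428, 0.0428 and 0.0401 became 0.302, 0.49, 0.512 and 0.117 with an estimated correlation.

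In all, 168 probe sets were called between restrained and control rats, 117 higher and 51 lower, naming 69 and 38 genes. With the BioC batch as a block 154 were called, and within the 13 BioC-low arrays 95, while the medians of the glucocorticoid-responsive, heat shock and immediate early lists were 0.67, 0.31 and 0.32 with the block and 0.67, 0.31 and 0.33 within those arrays. The count was 81 without control rat 2, 76 without control rat 3, 103, 69 and 83 without stress rats 1, 2 and 4, 42 without control rats 1 and 2 together, and 259 with the beta-actin 3'/5' ratio as a covariate. With the values as deposited it was 54, with 85.2% higher against 69.6% after normalization. Those values move the median of all probe sets by 0.10 in this comparison. The same shift was -0.17 for linalool minus control, 0.05 and 0.32 for stress with linalool minus stress and minus linalool, 0.16 for stress with linalool minus control, 0.21 and -0.06 for the average stress and linalool effects, and 0.22 for the interaction.

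**Figure D1:**
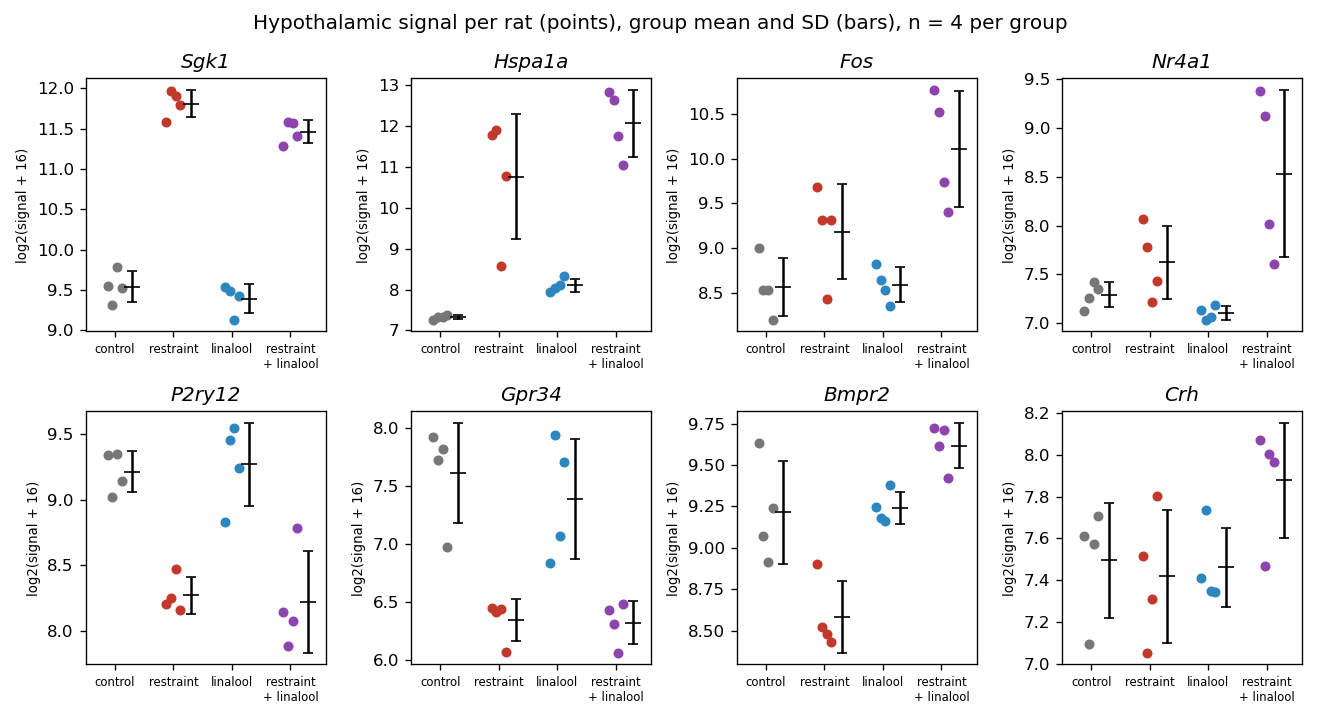
Signal of 8 genes on the log2(signal + 16) scale (vertical axis) in the 4 groups (horizontal axis), with 1 point per rat and the group mean with its SD beside the points (n = 4). Sgk1 averaged 11.81 and 11.46 in the groups with restraint against 9.54 and 9.39 without it, while Crh overlapped between all 4 groups.

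Restraint in the presence of linalool, compared with linalool alone, raised genes of the glucocorticoid-responsive, heat shock and immediate early lists. Sgk1 rose by 2.07 (SE 0.12, adjusted p = 1.67e-07), Pdk4 by 1.93, Ddit4 by 1.59, Tiparp, a target of the glucocorticoid and aryl hydrocarbon receptors, by 0.85, and Fkbp5 by 0.68. Hspa1a rose by 3.96 (SE 0.54, adjusted p = 0.0017), the small heat shock protein gene Hspb1 by 2.57 (SE 0.43, adjusted p = 0.00639), Dnajb1 by 1.74 and Hspb8 by 0.96. Fos, the classic marker of neuronal activation, rose by 1.52 (SE 0.29, adjusted p = 0.014), Jun by 1.31 (SE 0.20, adjusted p = 0.00336), Nr4a1 by 1.43 (SE 0.29, adjusted p = 0.0214), Fosb by 0.81 and Klf6 by 0.78. Crh (0.42, SE 0.17, adjusted p = 0.246) and Avp (0.03, adjusted p = 0.972) did not pass.

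Of the glucocorticoid-responsive list 16 members rose in this comparison and 0 fell (22 higher when adjusted over the list alone), with a median of 0.56 and an adjusted p = 0.0021 with an estimated correlation. For the heat shock list the counts were 9 and 0 (15 higher when adjusted over the list alone), the median was 0.33 and the adjusted p = 0.0224 with an estimated correlation. For the immediate early list they were 7 and 0 (18 higher and 1 lower when adjusted over the list alone), with a median of 0.63 and an adjusted p = 0.0224 with an estimated correlation. Clock genes Per1 (0.98), Per2 (0.54) and Nfil3 (0.88) rose, 3 of 20 measured, and so many also when adjusted over the list alone; the clock list's camera adjusted p of 0.00485 became an adjusted p = 0.243 with an estimated correlation. Nfkbia (1.09), Giot1 (1.43), Ch25h, which makes 25-hydroxycholesterol (1.42), and the astrocyte connexin gene Gjb6 (0.40) rose too. P2ry12 fell by 1.05 (adjusted p = 0.00629), Cx3cr1, the fractalkine receptor of microglia, fell by 0.69 (adjusted p = 0.0135), Gpr34 fell by 1.07 and Cd33 fell by 1.00. On the microglia list 2 of 11 fell and 0 rose, with 2 higher and 2 lower when adjusted over the list alone, 8 of the 11 changes were positive, and the list's median of 0.27 did not pass (camera adjusted p = 0.462). Hes5, a Notch target, fell by 1.14 (adjusted p = 0.00409), Nrarp fell by 0.85 and Sox18, an endothelial transcription factor, fell by 1.04. Ccdc77, Tmem234, Zfp324 and Prr5l fell by 0.82 to 1.60, and the neuropeptide gene Tac3 fell by 0.48.

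Here 314 probe sets were called, 209 higher and 105 lower, naming 131 and 87 genes. With the BioC batch as a block 499 were called, within the BioC-low arrays 74, and within the 3 BioC-high arrays, 8; the last fit sets a single restrained rat against 2 linalool rats, gives no spread for that rat's group and describes that rat alone. The medians of the glucocorticoid-responsive list were 0.57, 0.59 and 0.66 in these fits, those of the heat shock list 0.35, 0.34 and 0.53, and those of the immediate early list 0.64, 0.60 and 0.70. The count was 144 and 126 without linalool rats 1 and 3, 117 and 112 without stress with linalool rats 1 and 2, and 475 without control rats 1 and 2. With the values as deposited 1103 were called, 99.4% of them higher against 66.6% after normalization.

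Changes with restraint were set side by side with and without linalool, in comparisons that share no arrays. Across 18625 probe sets, which are not independent replicates, the log2 changes correlated with Pearson's r = 0.37 and Spearman's rho = 0.27 (exact one-sided permutation p = 0.000408 over 4900 assignments of the labels). Within the BioC-low arrays r was 0.33, and with the batch as a block 0.37. Of the probe sets called higher, 117 and 209, 63 were shared, against 1.31 for independent lists, and of those called lower, 51 and 105, 14 were shared, against 0.29. Of the 117 higher without linalool, 113 also had a positive change with it, and of the 51 lower, 36 had a negative one.

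**Figure D2:**
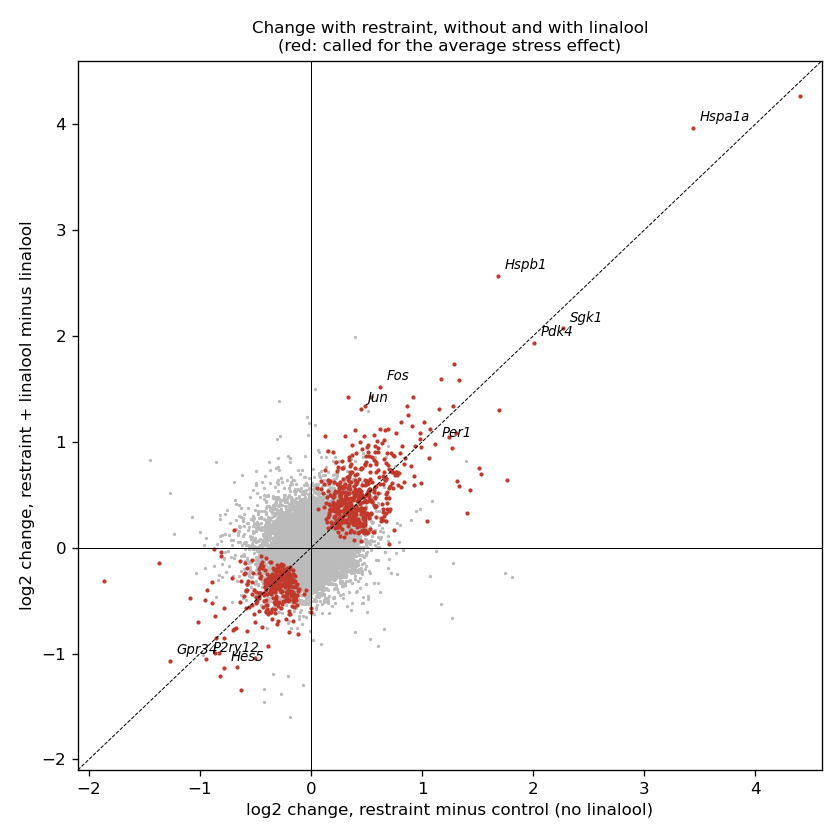
Log2 change with restraint in rats without linalool (horizontal axis) and with linalool (vertical axis), 1 point per probe set, with the 784 probe sets called for the average stress effect in red and a dashed line of equal change. Sgk1 lies near the line at 2.27 and 2.07, and Fos above it at 0.62 and 1.52.

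Averaged over rats with and without linalool, restraint changed more genes than either comparison alone could call. Hspa1a rose by 3.70 (SE 0.38, adjusted p = 4.35e-05), Sgk1 by 2.17 (SE 0.08, adjusted p = 3.81e-10), Hspb1 by 2.13 (SE 0.31, adjusted p = 0.000794), Pdk4 by 1.97, Dnajb1 by 1.51 and Ddit4 by 1.46. Of the glucocorticoid-responsive list 22 of 30 rose (26 higher when adjusted over the list alone; adjusted p = 0.000686 with an estimated correlation), among them Errfi1 (1.10) and Fkbp5 (0.81). Of the heat shock list 15 of 24 rose (21 higher when adjusted over the list alone; adjusted p = 0.0179 with an estimated correlation), among them Hspb8 (0.77) and Cryab (0.72). Of the immediate early list 11 of 26 rose (18 higher and 1 lower when adjusted over the list alone; adjusted p = 0.0366 with an estimated correlation), among them Fos (1.07, SE 0.20, adjusted p = 0.00691), Nr4a1 (0.88), Jun (0.88), Gadd45g (0.73), Fosb (0.69) and Klf6 (0.63). Per1 (1.05), Per2 (0.49) and Nfil3 (0.81) rose while Dbp, another clock output gene, fell by 0.30. Genes of oxidative and hypoxic stress rose in 5 of 20 cases, as many as when adjusted over the list alone, including Ddit3 (0.43), Srxn1 (0.43), Hmox1 (0.80) and the glucose transporter gene Slc2a1 (0.31), and the list's camera adjusted p of 0.0389 became an adjusted p = 0.108 with an estimated correlation. Nfkbia (1.20), Il1r1 (0.49), Ch25h (1.17) and Ccdc117 (1.10) rose as well.

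Gpr34 fell by 1.17 (SE 0.16, adjusted p = 0.000592), P2ry12 fell by 1.00 (SE 0.12, adjusted p = 0.000237), Cd33 fell by 0.93 (SE 0.11, adjusted p = 0.000112) and Bin2 fell by 0.86. On the microglia list P2ry12 and Cx3cr1 fell (Cx3cr1 fell by 0.49) and the other 9 of 11 did not pass, with 2 lower and 0 higher when adjusted over the list alone. Hes5 fell by 0.96 (adjusted p = 0.000326), Nrarp fell by 0.85, Sox18 fell by 0.77, Tmem234 fell by 0.90, Fgfrl1 fell by 0.74, and Opalin, a gene of myelinating oligodendrocytes, fell by 0.76 (SE 0.19, adjusted p = 0.0305). Slco1a4, a transporter gene of brain endothelium, fell by 0.34, Tac3 fell by 0.41, the glutamate transporter gene Slc1a1 fell by 0.24 and the mitochondrial gene Ndufv2 fell by 0.21, while Gjb6 rose by 0.29. Crh (0.17, SE 0.12, adjusted p = 0.495) and Avp (0.03, SE 0.16, adjusted p = 0.945) did not pass.

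The 784 probe sets called for the average stress effect, 493 higher and 291 lower, named 291 and 238 genes, with 3 in both directions. There were 997 calls with the BioC batch as a block and 457 within the BioC-low arrays, 510 and 517 without stress rats 1 and 2, 518 and 489 without linalool rats 1 and 3, and 522 without stress with linalool rat 2. The glucocorticoid-responsive, heat shock and immediate early lists had medians of 0.66, 0.31 and 0.54 with the block and 0.66, 0.31 and 0.50 within the BioC-low arrays. With the values as deposited 1035 were called, 98.2% of them higher against 62.9%.

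Linalool without restraint gave no call against the control group. With limma, 0 of 18625 probe sets passed, the smallest adjusted p was 0.282, and 1831 had an unadjusted p under 0.05 where 931 would be reached by chance. The 5 genes with the smallest p were Katnip (0.35, SE 0.07), Stard5 (-0.53, SE 0.11), Pros1 (-0.64, SE 0.13), Cd99 (0.54, SE 0.11) and Fyn (-0.42, SE 0.09), all with an adjusted p of 0.282. Somatostatin, Sst, differed by 0.50 (SE 0.11), complement C3 by -0.82 (SE 0.20) and Opalin by -0.66 (SE 0.26), none of them past the test. The 7 genes named for every comparison lay between -0.19 (Nr4a1) and 0.16 (Fkbp5). Camera called the lists of neuropeptides (median 0.14), heat shock genes (0.12; -0.032 with the values as deposited and 0.14 relative to their shift of all probe sets), oxidative phosphorylation (0.07; -0.058 and 0.11 in the same way), inflammation (-0.18), oligodendrocyte markers (-0.20) and endothelial markers (-0.18), with 0 members past the test over all probe sets. When adjusted over the list alone, 1 neuropeptide gene and 1 heat shock gene were higher and 2 inflammation genes lower. For each of these lists the result became an adjusted p = 0.61 with an estimated correlation, and with the BioC batch as a block the camera adjusted p was 0.0572 to 0.189. With 1 array left out, the highest camera adjusted p of a list was 0.0905 (heat shock genes) to 0.467 (oligodendrocyte markers). The neuropeptide median then ran from 0.066 to 0.25. The count of calls stayed at 0 with that block (1658 at unadjusted p under 0.05) and within the BioC-low arrays (1564 at unadjusted p under 0.05), and was 1 with the beta-actin ratio as a covariate and 2 without control rats 1 and 2.

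Among restrained rats, those that inhaled linalool had higher values than those that did not for most called probe sets. Bmpr2, a receptor of bone morphogenetic proteins, rose from 8.58 ± 0.22 to 9.62 ± 0.14 (n = 4; log2 1.03, SE 0.14, adjusted p = 0.00569), and Cutal rose by 1.07 (SE 0.15, adjusted p = 0.00569). Vof16 (1.01), Csrnp3 (0.96), Emg1 (0.98), the unconventional myosin gene Myo10 (0.93), Tspyl4 (0.85), the RNA helicase gene Ddx6 (0.85) and the chromatin gene Setd5 (0.84) rose. Genes of inhibitory transmission were among them: Gad2, which makes GABA, rose by 0.77 (SE 0.14, adjusted p = 0.0201) and Gabra2, a GABA-A receptor subunit, by 0.96 (SE 0.21, adjusted p = 0.0454). These were 2 of 17 measured genes on the GABA list, 2 also when adjusted over the list alone, and the list's median of -0.035 did not pass (camera adjusted p = 0.199). Cplx2, of synaptic vesicle release (0.67), and RT1-DMa, of antigen loading (0.46), rose. Sbf2, Ganc, Epc2, Slc31a2 and Tia1 fell by 0.49 to 0.95. In mean normalized signal, some of the higher genes were low in restrained rats and near the controls with both treatments. In controls, restrained rats and rats with both, Vof16 stood at 554.6, 310.3 and 634.2. Emg1 stood at 143.8, 66.88 and 153.7, and Tspyl4 at 2844, 1663 and 3000. Others stood above the controls with both, such as Cutal (61.01, 52.8 and 129.4) and Setd5 (311.8, 274.7 and 501.6). All these genes were chosen for higher values with both treatments than with restraint alone. That choice favours low values in the restrained rats, so these means do not by themselves show a return to the control level.

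Sgk1, Fkbp5 and Per1, which rose with restraint, did not pass between these groups. Differences were -0.35 (SE 0.12, adjusted p = 0.21) for Sgk1, -0.09 for Fkbp5 and -0.05 for Per1, and 0.46 for Crh (SE 0.17, adjusted p = 0.27) and -0.13 for Avp (adjusted p = 0.869). Values for Fos (0.93, SE 0.29, adjusted p = 0.167), Nr4a1 (0.91, SE 0.29, adjusted p = 0.19), Jun (0.69), Fosb (0.46), Hspb1 (1.32, SE 0.43, adjusted p = 0.194), Bag3 (0.66) and Dnajb1 (0.66) were higher with linalool without passing. In each of these genes the highest values were those of rats 1 and 2 with both treatments. Fos was at 10.77 and 10.53 in them and at 9.73 and 9.40 in rats 3 and 4, against 8.42 to 9.68 in restrained rats without linalool. None of 26 immediate early genes was called, 5 were higher when adjusted over the list alone, and the list's median of 0.23 (camera adjusted p = 1.71e-06) had an adjusted p = 0.595 with an estimated correlation. The heat shock list (median 0.15, camera adjusted p = 1.42e-06, 0 members called and 0 when adjusted over the list alone) also had an adjusted p = 0.595 with an estimated correlation. The medians of the immediate early and heat shock lists were 0.20 and 0.15 with the BioC batch as a block and 0.15 and 0.14 within the BioC-low arrays.

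Of the 121 probe sets called, 111 were higher and 10 lower, naming 87 and 7 genes. The 3 BioC-high arrays include 1 of the 4 rats with both treatments, and within the BioC-low arrays limma called 0 probe sets, with 1692 at unadjusted p under 0.05, while 51 were called with the batch as a block. The median change of the 111 probe sets was 0.73 with a median SE of 0.13 over all arrays, and 0.69 with a median SE of 0.14 within the BioC-low arrays, values raised by the choice of these probe sets on the same rats. The count was 182, 33, 38 and 44 without stress rats 1 to 4 and 59, 29, 42 and 67 without stress with linalool rats 1 to 4, 250 without control rats 1 and 2, and 386 with the beta-actin ratio as a covariate. With the values as deposited it was 32, of which 31 were higher.

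**Figure D3:**
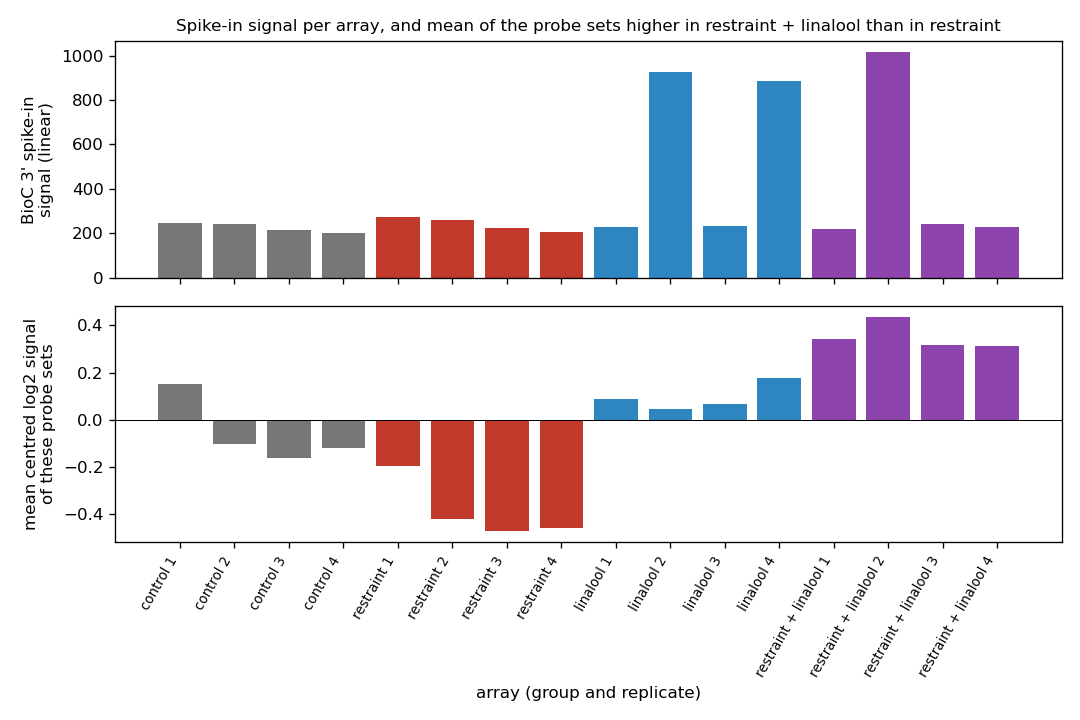
BioC 3' spike-in signal on a linear scale (upper bars) and the mean of the 111 probe sets called higher in restrained rats with linalool than without, centred over all arrays, in log2 (lower bars), for each of the 16 arrays. The spike-in is high on 3 arrays, between 884.4 and 1014, and the lower bars run from 0.31 to 0.44 in the 4 rats with both treatments and from -0.47 to -0.20 in the restrained rats.

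Averaged over restrained and unrestrained rats, linalool raised Emg1 (0.71, SE 0.15, adjusted p = 0.0437), Gabra2 (0.69, SE 0.15, adjusted p = 0.0437), Cutal (0.67, SE 0.11, adjusted p = 0.0126), Myo10 (0.65), Setd5 (0.62), the phosphatase gene Ppp4c (0.62), Csrnp3 (0.57), C10h17orf75 (0.54), Vof16 (0.54) and Bmpr2 (0.53). Ptpru, a receptor tyrosine phosphatase gene, fell by 0.49 (SE 0.10, adjusted p = 0.0338), and Rnf32, Rassf3, Stard5, Arhgef2, Stard8, Dclre1b, Slc31a2, Arfgap3 and Myh9 fell by 0.33 to 0.45. Sst rose by 0.37 (SE 0.08, adjusted p = 0.0421), 1 of 27 measured neuropeptide genes, with 2 higher when adjusted over the list alone; the list's camera adjusted p of 0.0123 became an adjusted p = 0.739 with an estimated correlation. RT1-DMa rose by 0.36. At the preset correlation, camera also called the heat shock, immediate early and oxidative phosphorylation lists. With 1 array left out, their medians ran from 0.105 to 0.157, 0.066 to 0.15 and 0.035 to 0.064. Their highest camera adjusted p was then 4.84e-05, 0.106 and 0.0411. For some genes the estimate was larger among restrained rats. Bmpr2 and Vof16 changed by 0.03 and 0.08 in linalool minus control, without passing, against 1.03 and 1.01 among restrained rats. The latter values are raised by the choice of these genes as large rises there. The interaction passed for neither gene, so a different effect of linalool in restrained and unrestrained rats is not shown. Values of Crh (0.21, adjusted p = 0.441), Fos (0.48, adjusted p = 0.288) and Sgk1 (-0.25, adjusted p = 0.183) did not pass.

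This average effect had 133 calls, 111 higher and 22 lower, naming 84 and 18 genes. Limma gave 1 call when the BioC batch was a block and 0 within the BioC-low arrays, where 1760 had an unadjusted p under 0.05. The median change of the 111 higher probe sets, chosen on all arrays, was 0.45 over all arrays (median SE 0.09), 0.44 with the block (median SE 0.10) and 0.44 within the BioC-low arrays (median SE 0.10). Leaving out as many other arrays of the same groups gave 1, 0 and 0 calls, so the BioC-low arrays left no fewer calls than most equal reductions did. The values as deposited gave 1 call, which was lower, against 83.5% higher after normalization. Leaving out 1 array gave 366 without control rat 1, 79 without control rat 3, 79, 48 and 82 without stress rats 2, 3 and 4, 75, 66, 63 and 40 without linalool rats 1 to 4, and 63, 37, 75 and 72 without stress with linalool rats 1 to 4. Linalool's changes in restrained and in unrestrained rats, which share no arrays, correlated with r = 0.18 and rho = 0.19 (exact one-sided permutation p = 0.0437 over 4900 assignments), across probe sets. That r was 0.13 with the batch as a block and 0.046 within the BioC-low arrays.

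Of the treated groups, rats with both treatments had the most calls against untreated controls. Hspa1a rose by 4.74 (SE 0.54, adjusted p = 0.000214), Hspb1 by 3.01 (SE 0.43, adjusted p = 0.00142), Pdk4 by 2.12, Dnajb1 by 1.95, Sgk1 by 1.92 (SE 0.12, adjusted p = 5.14e-07), Ddit4 by 1.56, Fos by 1.55 (SE 0.29, adjusted p = 0.00785), Nr4a1 by 1.24, Per1 by 1.06, Fkbp5 by 0.84 and Bag3, a cochaperone induced by heat, by 1.47. Cebpd (1.34) and Cebpb (1.30), transcription factors induced by glucocorticoids and cytokines, and Hmox1 (1.11) rose. Of the glucocorticoid-responsive, heat shock and immediate early lists, 18, 16 and 10 members rose and 0 fell, with 26, 20 and 16 higher when adjusted over the list alone and adjusted p = 0.00236, 0.0151 and 0.0476 with an estimated correlation. Opalin fell by 1.31 (SE 0.26, adjusted p = 0.0121) and Cnp, of myelin, fell by 0.43, 2 of 15 oligodendrocyte markers, with 2 lower when adjusted over the list alone. Slco1a4 fell by 0.60 and the pericyte gene Pdgfrb fell by 0.69, 2 of 13 endothelial and mural markers, with 4 lower when adjusted over the list alone. Gpr34 fell by 1.29, Tmem234 fell by 1.26, Nrarp fell by 1.15, Sox18 fell by 1.10, Hes5 fell by 1.09, Cd33 fell by 1.05, Eml2 fell by 1.03, P2ry12 fell by 0.99, Dbp fell by 0.47 and Rbm3, a cold-inducible RNA-binding protein gene, fell by 0.96 (SE 0.17, adjusted p = 0.00563). Foxj1, of ciliated ependyma, rose by 0.79, and Crh (0.38, adjusted p = 0.245) and Avp (-0.09, adjusted p = 0.88) did not pass.

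This comparison called 748 probe sets, 457 higher and 291 lower, naming 256 and 225 genes with 1 in both directions. The count was 445 with the BioC batch as a block, 215 within the BioC-low arrays, 407 without control rat 3, and 359, 259 and 492 without stress with linalool rats 1, 2 and 3. It was 441 without control rats 1 and 2, and 203 in a fit of only these groups. The medians of the glucocorticoid-responsive, heat shock and immediate early lists, 0.70, 0.50 and 0.62, were 0.65, 0.47 and 0.56 with the block and 0.63, 0.45 and 0.55 within the BioC-low arrays. With the values as deposited it was 311, with 94.2% higher against 61.1%.

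**Figure D4:**
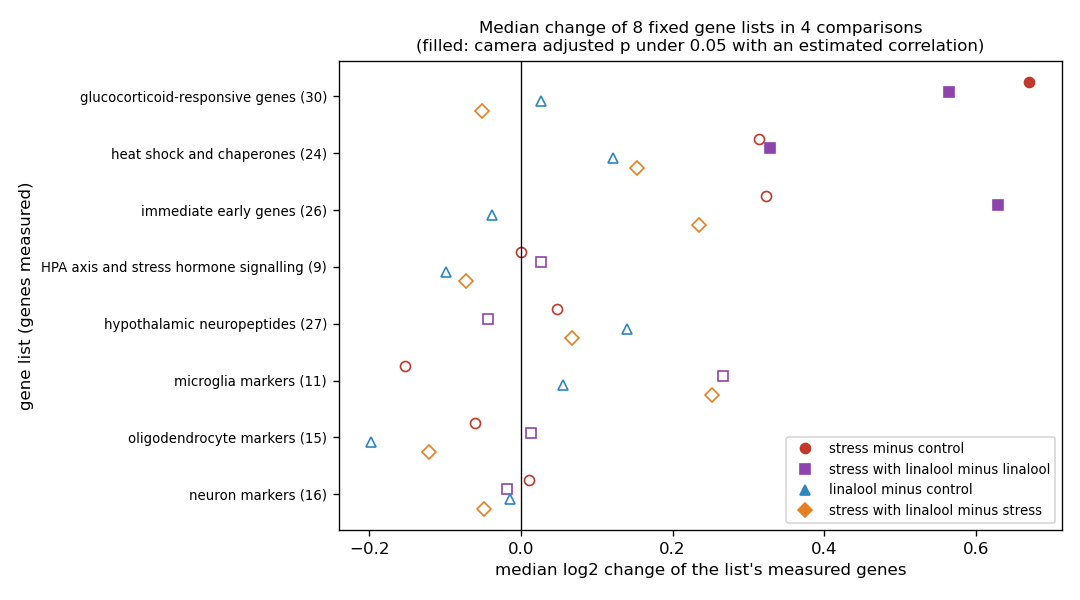
Median log2 change (horizontal axis) of the measured genes of 8 fixed lists (vertical axis, with the number of genes measured) in 4 comparisons, 1 symbol per comparison, filled where camera's adjusted p is under 0.05 with an estimated correlation. The glucocorticoid-responsive list stands at 0.67 and 0.56 in the comparisons with restraint and at 0.03 and -0.05 in those with linalool.

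Whether linalool altered the response to restraint was asked of the interaction. With limma, 0 of 18625 probe sets passed, the smallest adjusted p was 0.0565, and 1489 had an unadjusted p under 0.05 where 931 would be reached by chance. The smallest p belonged to Inpp5b, an inositol phosphatase gene, whose level was 9.54 ± 0.09 in controls, 8.84 ± 0.13 with restraint, 9.24 ± 0.11 with linalool and 9.41 ± 0.11 with both (interaction 0.87, SE 0.12, adjusted p = 0.0565). It was followed by Katnip (-0.59), Bmpr2 (1.01), Cdkl2 (-0.74) and She (-0.63), with adjusted p of 0.135 to 0.309. Interaction values were -0.20 (SE 0.17, adjusted p = 0.798) for Sgk1, 0.90 (SE 0.41, adjusted p = 0.612) for Fos, 1.09 (SE 0.42, adjusted p = 0.559) for Nr4a1, 0.86 (SE 0.28, adjusted p = 0.494) for Jun and 0.49 (SE 0.25, adjusted p = 0.637) for Crh. The immediate early list had a median interaction of 0.25, with 0 members called, 0 also when adjusted over the list alone, and a camera adjusted p of 3e-05 that became an adjusted p = 0.429 with an estimated correlation. Camera also called the inflammation, glutamate, clock, microglia and pituitary lists. With 1 array left out, their medians ran from 0.11 to 0.51, 0.087 to 0.20, 0.087 to 0.18, 0.15 to 0.58 and -0.74 to -0.24. Their highest camera adjusted p was then 0.0911, 0.0832, 0.0771, 0.13 and 0.343.

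Over the 784 probe sets called for the average stress effect, the median change in the direction of that effect was 0.37 without linalool and 0.42 with it. The median signed interaction was 0.05 (exact two-sided permutation p = 0.471 over 4900 assignments), so that a smaller restraint response with linalool was not detectable. With the BioC batch as a block this value was 0.10 (permutation p = 0.0322). Within the BioC-low arrays it was 0.16 (permutation p = 0.0133), and both lie toward a larger change with linalool. Neither fit is balanced over the groups, so choosing probe sets by the average stress effect on the same arrays can itself shift this value. Within the BioC-low arrays that choice pushes it upward. The block was also removed with the real groups before the labels were permuted. Neither p-value therefore shows a larger response with linalool. Without control rat 4 the signed interaction was -0.011. The number of called interactions was 14 with the beta-actin ratio as a covariate and 1 with the batch as a block, with the values as deposited, without control rats 1 and 2, and without stress with linalool rat 3.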

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

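The tests of the explanations below were chosen after the results were seen, except the replacement of left-out arrays and the test of Cirbp, whose bounds were written before their values were known, although the counts with 1 array left out had been seen by then. The bound for low values in the restrained rats was reworded after its result was seen, and the rule that Cirbp must clear its bound by 2 standard errors was added after its value was seen. The BioC 3' spike-in signal, which no comparison uses, was 927.5 and 884.4 on linalool arrays 2 and 4 and 1014 on stress with linalool array 2, against 201.3 to 245.6 on the control arrays. The GAPDH 3'/5' ratio of control rat 1 was 1.394, far from the 1.139 to 1.16 of the other controls.

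Among 436 groups of 4 tested over array quality and the genes named in the report, 26 had a rat far from the other 3, where chance gives about 21.8. In controls these were, in log2 signal, Cebpd at 6.29 and Myo10 at 7.86 in rat 1, Per1 at 6.86 and Rbm3 at 10.21 in rat 2, and Dnajb1 at 9.62 and Nrarp at 9.43 in rat 4. In restrained rats they were Ddx6 at 10.06 and Pdk4 at 9.38 in rat 1, Cebpb at 6.39, Cplx2 at 7.04, Hspa5 at 12.36 and Sox18 at 7.80 in rat 3, and Gpr34 at 6.07 in rat 4. In linalool rats they were Cx3cr1 at 7.34 and Prr5l at 7.41 in rat 1, Cebpb at 6.29 and Ndufv2 at 11.36 in rat 2, Ch25h at 7.32 in rat 3, and Hmox1 at 6.40 and Katnip at 6.58 in rat 4. In rats with both they were Cutal at 7.57 in rat 1, Gjb6 at 10.6 and Slc31a2 at 6.24 in rat 2, and Stard5 at 6.499 and Tac3 at 7.50 in rat 3.

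Other splits of the same rats were counted for each comparison. The real split was 1 of 35 with as many calls for stress minus control (168, highest other split 2), stress with linalool minus stress (121, highest other 2), stress with linalool minus linalool (314, highest other 1) and stress with linalool minus control (748, highest other 1), so that an accidental division of these rats is argued against. The same held with 1 of 100 splits for the average stress effect (784, highest other 158) and the average linalool effect (133, highest other 1). For linalool minus control all 35 splits, and for the interaction all 100, gave as many calls as the real one (0, highest other 2 and 1), which a count of 0 makes certain, so that these splits say nothing on chance.

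Restrained rats with linalool had 111 probe sets higher than restrained rats without it. The spike-in batch as the whole cause of such differences is argued against by rats held out of the choice of probe sets. In each of 18 ways, 111 probe sets were picked anew in the BioC-high rat, 1 BioC-low rat and 2 restrained rats. They changed by a median of 0.50 in the other BioC-low and restrained rats (median SE between rats 0.12, range 0.29 to 0.57). The 18 ways share rats. Their picks need not be the 111 called probe sets, for which the batch was not tested in this way. Yet no call is left within the BioC-low arrays, while leaving out as many BioC-low arrays of the same groups in their place left 19, 19 and 27. By the bound written before, fewer arrays alone would not account for this. The replacements all leave out the same linalool rats, however, and counts at a threshold vary, so they cannot exclude a loss of power. The median change of the 111 called probe sets was 0.69 (SE 0.14) within the BioC-low arrays and 0.73 to 0.74 (SE 0.15) in the replacements. The change thus stayed about as large, and why the calls ended is not settled. Whether RNA quality played a part cannot be told from the beta-actin 3'/5' ratio. The median change was 0.74 with that ratio as a covariate, but these 111 probe sets were chosen on the same arrays. The ratio averaged 3.21 in restrained rats and 2.90 in rats with both treatments, so as a covariate it could hardly move this median. Low values in the restrained rats without any effect of linalool stay open, because the same probe sets changed by a median of 0.14 in linalool minus control (exact one-sided p = 0.0714).

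P2ry12, Gpr34 and Cd33 fell with restraint by a median of 1.00. A smaller share of microglia would lower the other microglia markers alike. The other 10 on the fixed list changed by a median of 0.13 (standard error over these genes 0.10). Of them, Cx3cr1 fell by 0.49 (adjusted p = 0.00603) and none of the 7 with higher values passed. The median of the 10 was -0.10 without linalool and 0.29 with it (standard errors over genes 0.10 and 0.15). For the 3 genes it was -0.95 and -1.05. These standard errors treat the genes as independent and leave out the spread between rats. Bin2 and Plek, genes of blood-derived and microglial cells outside the fixed list, also fell with restraint alone. Reshaping of the distributions by quantile normalization is argued against, because with the values as deposited the 3 genes changed by -0.98 relative to the median of all probe sets. That median itself moved by 0.21, so this measure still takes out a level difference between arrays and does not test it. A change of these transcripts within microglia may be at work, as a hypothesis found and tested on the same data, and a smaller share of microglia is not excluded.

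Heat shock genes were higher and Rbm3, whose transcript falls with warming, was lower in restrained rats (-0.73, SE 0.12, adjusted p = 0.00218). A few extreme rats as the whole cause are argued against. The mean of the heat shock list was still 0.48 higher without the 3 highest restrained rats (SE between rats 0.10, against 0.62 with all of them). RNA quality cannot be decided by the beta-actin ratio here. That ratio averaged 3.21 and 2.90 in the groups with restraint and 3.07 and 3.09 in those without. As a covariate it could thus hardly move the median of the heat shock list, which was 0.31 with and without it. A warmer hypothalamus in restrained rats is a candidate explanation that stays open, because Cirbp, the other cold-inducible gene of this kind, changed by -0.076 (SE 0.10), a value whose error covers both a fall and none. No body temperature was analysed here.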

How the results depend on the processing

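Quantile normalization, the spike-in batch, the beta-actin covariate and the fit without control rats 1 and 2 were chosen after seeing the data, whereas the values as deposited are the setting fixed before, and the cause was not tested for the differences below, except for fewer arrays in stress with linalool minus stress and the average linalool effect. All 173 pairs of a called gene and a comparison named in the text kept their direction under every alternative that kept the gene, with 1915 values still past the threshold and 415 not, and with 1481 and 430 when 1 array was left out. Of the 173 pairs, 95 lost their call within the BioC-low arrays, 69 with the values as deposited, 53 without the filter on dim probe sets, 41 without control rats 1 and 2 and 37 with the BioC block. The BioC-high arrays lost 30 of 33, and leaving out stress with linalool rat 2 lost 61 of 146, the most for any 1 array.

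Calls are given in the order of stress minus control, stress with linalool minus stress, minus linalool and minus control, and the average linalool effect. They were 102, 46, 188, 428 and 31 without a filter, with r = 0.24 for the stress effects. Array weights gave 72, 484, 594, 500 and 236. Only the groups compared gave 53 and 203 for stress minus control and stress with linalool minus control. The values as deposited gave 54, 32, 1103, 311 and 1. The BioC block gave 51, 499, 445 and 1 for the last 4, and the BioC-low arrays 95, 0, 74, 215 and 0, with 457 for the average stress effect, r = 0.046 for the linalool effects, and the BioC-high arrays 8 for stress with linalool minus linalool. The beta-actin covariate gave 259, 386, 553, 1061 and 327, and the fit without control rats 1 and 2 gave 42, 250, 475, 441 and 246. Linalool minus control had 1 and 2 calls in these last fits. The interaction had 14 with the covariate and 1 with a pseudocount of 64, a filter at the 60th percentile, median centring, the trended robust fit, the values as deposited, the BioC block, and without both control arrays. The signed interaction was 0.10 with the BioC block and 0.16 within the BioC-low arrays.

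With 1 array left out, the counts ran from 69 to 202, 29 to 182, 112 to 368, 259 to 1046 and 37 to 366 in that order, from 489 to 1004 for the average stress effect, from 0 to 1 for the interaction, and stayed at 0 for linalool minus control. The correlations ran from 0.31 to 0.39 and 0.12 to 0.22, and the signed interaction from -0.011 to 0.12.

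The replicate number as a block gave 84 calls for the average linalool effect and moved no other count by over 1.5 times. The labels do not say whether the numbers pair the rats. Deviations over all kept probe sets correlated by -0.16 to 0.23 for same-numbered rats (median 0.00, 24 pairs). Those of other rats correlated by -0.25 to 0.21 (median -0.01, 72 pairs). Such correlations cannot exclude a link in fewer genes. The mean of the heat shock list was highest in rats 1 and 2 of both restrained groups (10.52 and 10.68, and 10.86 and 10.87 with linalool). In the control and linalool groups rats 1 and 2 were not the highest.

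Signs turned for the signed interaction without control rat 4 (-0.011), for genes that did not pass and for lists not past the test with an estimated correlation. With the values as deposited, oxidative phosphorylation stood at 0.046 for stress minus control, -0.058 for linalool minus control, 0.21 for stress with linalool minus linalool and 0.13 for the average stress effect, the heat shock list at -0.032 for linalool minus control, Crh at 0.013 for stress minus control, Fkbp5 at -0.028 for linalool minus control, Per1 at 0.007 for stress with linalool minus stress, Avp at 0.082 for stress with linalool minus control and Sgk1 at 0.095 for the interaction. These values also move the median of all probe sets, and relative to that shift all 10 of these results kept the sign they had after normalization. Median centring gave -0.041 for the astrocyte list and -0.068 for Avp in stress with linalool minus linalool and -0.031 for Avp on average, and array weights -0.009 for Avp in stress minus control. Avp was 0.02 and 0.056 within the BioC-low arrays against stress and control, and Avp was -0.57 and Crh -0.069 within the BioC-high arrays. With 1 array left out, Avp ran from -0.094 to 0.11 on average, -0.064 to 0.12, -0.19 to 0.056, -0.22 to 0.18 and -0.21 to 0.02 for stress minus control and for stress with linalool minus control, minus linalool and minus stress, Crh from -0.21 to 0.047 for stress minus control, Fkbp5 from -0.004 to 0.26 for linalool minus control, Per1 from -0.15 to 0.075 for stress with linalool minus stress, and the inflammation list from -0.001 to 0.16 on average.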

Other observations

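Other genes of signalling and of cell types fell in restrained rats on average over the odour conditions, chosen here after their values were seen. Beside Hes5 and Nrarp, the Notch target Hey2 fell by 0.42 (SE 0.08, adjusted p = 0.00663, but 0.276 without linalool), while Hes1 (0.17, adjusted p = 0.434), Hey1 (-0.11, adjusted p = 0.38), Heyl (-0.33, adjusted p = 0.0742) and the receptor gene Notch1 (0.06, adjusted p = 0.733) did not pass. Beside Sox18, the endothelial genes Sox7 and Egfl7 fell by 0.45 (adjusted p = 0.0158) and 0.46 (adjusted p = 0.0159), and Sox17 (-0.32, adjusted p = 0.18) and Tie1 (-0.09, adjusted p = 0.69) did not pass. Neither Sox7 (adjusted p = 0.214 and 0.0877) nor Egfl7 (adjusted p = 0.0721 and 0.238) passed without or with linalool alone. The fixed endothelial and mural list did not shift past the test, with 1 of 13 lower, 4 lower when adjusted over the list alone and a median of -0.029 (camera adjusted p = 0.68).

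In the oligodendrocyte lineage, the transcription factor genes Nkx6-2 and Nkx2-2 fell by 0.68 (adjusted p = 0.00222) and 0.43 (adjusted p = 0.0181) and Gal3st1, which makes the myelin lipid sulfatide, fell by 0.43 (adjusted p = 0.0469). Without and with linalool alone, Nkx2-2 (adjusted p = 0.0806 and 0.237) and Gal3st1 (adjusted p = 0.435 and 0.117) did not pass, and Nkx6-2 passed without it (adjusted p = 0.0271) and not with it (adjusted p = 0.0814). The fixed oligodendrocyte list did not shift past the test, with 1 of 15 lower, 2 lower when adjusted over the list alone and a median of -0.036 (camera adjusted p = 0.36). The myelin genes Mag (0.01, adjusted p = 0.976) and Mog (-0.04, adjusted p = 0.894) did not pass. Hspa1a stood at 8.10 ± 0.16 in linalool rats and 7.33 ± 0.05 in controls (n = 4), with a difference of 0.78 that did not pass in limma's test (SE 0.54, adjusted p = 0.653). That SE is pooled over all groups and so holds the spread of the restrained rats, from 8.59 to 11.90 in those without linalool. Every linalool rat (7.94 to 8.33) lay above every control (7.26 to 7.39), so the missing call does not show an unchanged level.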
